A study of Mus musculus with 4 samples.

How the data were processed

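Polyadenylated RNA was sequenced from primary mouse macrophages grown from bone marrow. The cells had been exposed to RANKL, the cytokine that turns such precursors into osteoclasts, and were collected on day 2. By their labels the 4 libraries form 2 groups of 2, siControl and siHells, where siHells stands for an siRNA against Hells. The siRNA sequences and the number of animals or cultures behind the libraries are not given in the sources used here.

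The authors deposited whole-number read counts per gene symbol, in 1 table of 17194 symbols with a column for each library, and no normalization had been applied to them. Every column matched a labelled sample by name. The submitters' processing notes name FastQC, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and edgeR, and the mouse genome build mm10, without giving each tool's role. The annotation release and the strand setting of the counting are not given in the sources used here. Per the labels' protocols, the extraction text of every sample names 2 library kits, SMARTer mRNA-Seq and TruSeq Stranded mRNA, so it is open which kit made a library and whether the reads kept their strand. Genes with an overlapping or antisense neighbour, and genes with near-identical copies, are therefore uncertain. The lowest deposited count was 1 and the table held 0 values of 0, so genes with 0 reads in even 1 library were not analysed here. A gene that was silent in a group and on in the other would be among them.

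Total counts were 53502523 and 48873635 for siControl replicates 1 and 2 and 55642819 and 55012697 for siHells replicates 1 and 2. At this depth the minimum count of 10 used as a filter stands for 0.184 CPM. Intervals on ratios of summed counts are exact binomial intervals at a confidence level of 95% and cover counting error only.

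Genes were kept by edgeR's filterByExpr with its default minimum count of 10 and minimum total of 15, which removed 1543 genes and left 15651. Library sizes were scaled by TMM with its default trims of 0.3 and 0.05, and the factors were 1.03 and 1.02 for siControl and 0.974 and 0.975 for siHells. Differences were tested with the edgeR quasi-likelihood test in edgeR 4.0.16 (R 4.3.3), with robust dispersion estimates, the current rather than the legacy form of the quasi-likelihood fit, and group as the only term, which left 2 residual degrees of freedom. The common biological coefficient of variation was 0.0418. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are siHells over siControl. Expression levels are TMM-normalised CPM, given as mean ± SD over the 2 libraries of a group.

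Before the data were examined, 34 gene lists had been fixed. They covered osteoclasts, macrophages and cell fusion, mitochondria and energy metabolism, the cell cycle, stress, interferon and inflammation, chromatin and imprinting, other marrow cell types, and genes that respond to RNA handling. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 34 lists. The test was repeated with a correlation estimated for each list. That form rests on the 2 residual degrees of freedom, so it has little power. A list that does not pass it is not shown to be unchanged. Also fixed beforehand was the rule for the genes named: Hells and Nr2f2; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1, groups that do not overlap and a symbol that is not of the Gm or Rik kind; up to 4 members with the smallest p per list; and 14 genes of osteoclast formation, mitochondria and proliferation. Genes outside the rule are named to identify small counts, to mark an exception within a list or as examples of glucocorticoid targets, and these were chosen after their values were seen.

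Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling and library totals in place of TMM; no filter, or a filter of at least 1 CPM in 2 libraries and a mean count of 10; the DESeq2 Wald test (DESeq2 1.42.0), limma voom, the edgeR exact test and the legacy quasi-likelihood fit; the replicate number as a block; each library left out in turn; an adjusted p threshold of 0.01; a test against a 1.5-fold change; and, for lists, the estimated correlation and fry. Corrections for gene length and for GC content, made with lowess trends of span 0.3, were added after the data had been seen.

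Of the symbols, 96.8% matched a RefSeq symbol of GRCm38.p6, from which coordinates were taken, and 15652 matched a GENCODE M21 gene, from which exon length and GC content were taken. The procedure was tested on simulated counts for this comparison with 200 genes changed, of which the low-count filter kept 198. Of these the test recovered 36.0% at 1.2-fold, 66.7% at 1.5-fold, 92.0% at 2-fold and 94.0% at 4-fold. It made 152 calls among 15493 genes, of which 9 were false. In the data 9153 genes were called, far more than were changed in the simulation, so these rates may not hold there. In simulated gene lists, a list of 40 genes shifted by 0.5 on the log2 scale was called and 0 of 40 unchanged lists were. Genes were drawn independently there, so this does not test lists whose genes vary together.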

Results

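Polyadenylated RNA was sequenced from primary mouse macrophages grown from bone marrow, on day 2 of exposure to RANKL, the cytokine that drives these precursors toward bone-resorbing osteoclasts. Of the 4 libraries, 2 were labelled siControl and 2 siHells. The comparison asks which transcripts differ when Hells, a chromatin remodelling ATPase needed for normal DNA methylation, is depleted at this stage, and the series title names mitochondria and the nuclear receptor Nr2f2 as its subjects. Total counts were 53502523 and 48873635 in the siControl libraries and 55642819 and 55012697 in the siHells libraries. The libraries of a group differed by more than sampling noise, with a chi-square per gene of 3.59 over 13945 genes in siControl and of 6.69 over 13982 genes in siHells. Nothing in the labels says that they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Gene-level adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 15651 genes. Those of gene lists are from camera, adjusted over 34 lists.

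Hells, the siRNA target, was 1.99-fold lower in the siHells libraries, at 14.9 ± 0.390 CPM (SD, n = 2) against 29.7 ± 0.459 CPM in siControl (n = 2). Its counts were 1613 and 1501 in siControl and 823 and 785 in siHells, for a log2 fold change of -0.99 (SE 0.068, adjusted p = 5.96e-09). Hells is a protein-coding gene on chromosome 19, at 38930262 to 38970470 of GRCm38 on the plus strand.

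Nr2f2, an orphan nuclear receptor, rose 4.32-fold from a low level, from 0.498 ± 0.370 to 2.11 ± 0.264 CPM (SD, n = 2 each). Its counts were 13 and 38 in siControl and 104 and 123 in siHells, and its log2 fold change was 2.11 (SE 0.34, adjusted p = 9.20e-05). The ratio of summed counts was 4.33, with a 95% exact binomial interval of 3.19 to 5.99. Because the siControl counts differed, the change in Nr2f2 expression was 1.46 on the log2 scale without siControl replicate 1 and 3.14 without siControl replicate 2, and passed the threshold in both cases. The gene lies on chromosome 7 at 70351946 to 70366746 of GRCm38, minus strand, and is overlapped on the opposite strand by the noncoding B130024G19Rik, whose reads cannot be told from its own without strand.

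Over all genes, 4541 were higher and 4612 lower in siHells, together 58.5% of those tested. A change of at least 2-fold was found for 1056 genes that rose and 864 that fell. The osteoclast genes Mmp9, Ctsk and Acp5 were among the abundant transcripts that fell. The macrophage genes F13a1 and Stab1 and the adhesion molecule Vcam1 were among those that rose. The groups did not overlap in 12293 genes, 78.5% of those tested, where 33.3% is the share that chance gives for 2 libraries against 2. Against a change of 1.5-fold rather than 0, 1261 genes were higher and 1096 lower. No called gene changed sign under the other scalings. Genes named below to identify a small count or an exception within a list were chosen after their values were seen.

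**Figure D1:**
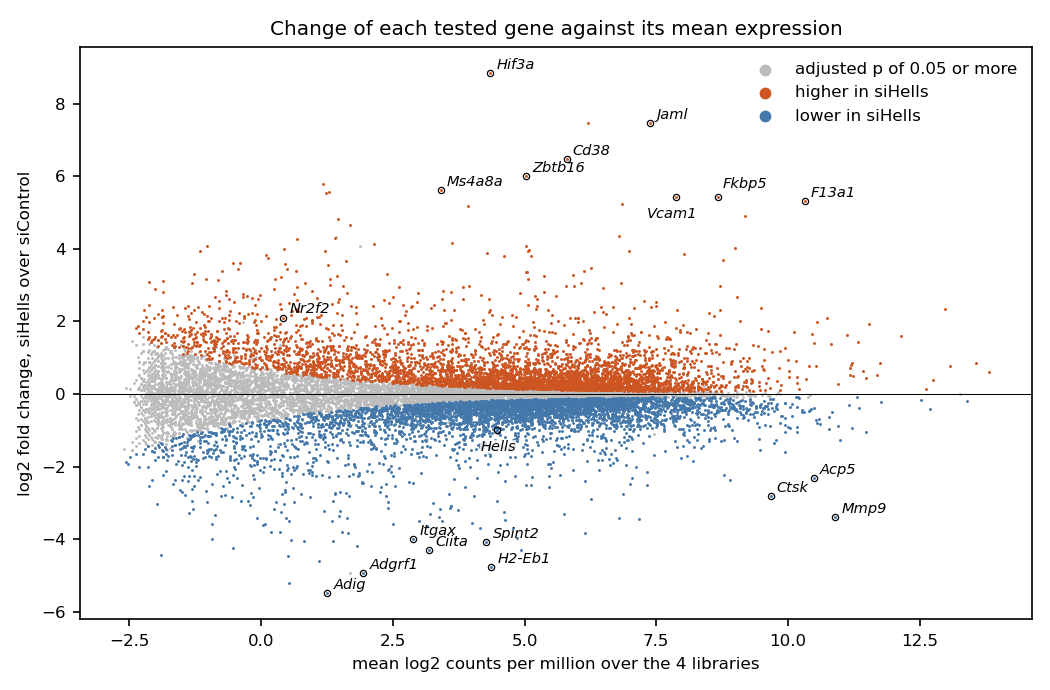
Log2 fold change of siHells over siControl against mean log2 CPM, with 1 point for each of the 15651 genes tested and colour for those with an adjusted p below 0.05. Hif3a stands highest at 8.84, Adig is at -5.48, and Mmp9, Ctsk and Acp5 fell at high expression.

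Genes of osteoclast differentiation and bone resorption fell together. Mmp9, a matrix metalloproteinase, fell 10.4-fold, from 3465 ± 7.13 to 334 ± 5.81 CPM. Ctsk, the collagen-degrading cathepsin K, fell 7.04-fold, from 1423 ± 23.1 to 202 ± 3.07 CPM, and Acp5, the tartrate-resistant acid phosphatase, fell 4.99-fold, from 2388 ± 6.09 to 479 ± 15.1 CPM (SD, n = 2 each; log2 fold change -3.37, SE 0.027, adjusted p = 9.55e-20 for Mmp9). Atp6v0d2, a subunit of the proton pump that osteoclasts use, fell 5.14-fold, Nfatc1, the master transcription factor of osteoclast formation, 1.93-fold, and Tnfrsf11a, the RANKL receptor, 1.49-fold. Of 38 tested members 35 fell and 2 rose, and the counts were the same when adjusted over the list alone. The 2 that rose were Fcer1g (log2 fold change 0.34) and Trem2 (0.19), both parts of immunoreceptor signalling. The list had a median log2 fold change of -1.36 and a camera adjusted p = 4.17e-13, against an adjusted p = 0.273 with an estimated correlation.

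Genes listed for the fusion of precursors into multinucleated cells also fell, 13 of 17 over all genes and 13 when adjusted over the list alone. The member with the smallest p, Atp6v0d2, is also on the osteoclast list, so the lists are not independent. Dcstamp, a membrane protein required for fusion, fell 4.23-fold, Src, the tyrosine kinase, 4.95-fold, the tetraspanin Cd9 4.04-fold and the exchange factor Dock5 2.76-fold. The 4 that rose were Adam12 (log2 fold change 2.00), Adam8 (0.40), Cd81 (1.70) and Cd47 (0.25). The median was -0.94, with a camera adjusted p = 0.00107 and an adjusted p = 0.273 with an estimated correlation.

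Genes of macrophage identity and of restraint of osteoclast formation rose. F13a1, the coagulation factor XIII A subunit made by macrophages, rose 39.5-fold, from 63.0 ± 0.618 to 2487 ± 7.62 CPM (SD, n = 2 each; log2 fold change 5.30, SE 0.031, adjusted p = 3.99e-21). Mertk, a receptor for apoptotic cells, rose 5.01-fold, the complement gene C1qa 3.94-fold and the scavenger receptor Stab1 3.84-fold. Mertk is also among the glucocorticoid targets described below. Irf8, a transcription factor that restrains osteoclast formation, rose 1.94-fold, and Csf1r, the receptor for macrophage colony-stimulating factor, 1.66-fold. Of 35 members 30 rose and 3 fell (31 and 3 when adjusted over the list alone). The 3 were Cd68 (log2 fold change -0.28), the chemokine receptor Ccr2 (-1.38) and Tnfaip3 (-0.10). Among markers of other marrow cells, the stromal genes Col1a1, Col1a2 and Acta2 were also higher, by 1.78-fold, 1.88-fold and 1.98-fold. The median of the macrophage list was 0.80, with a camera adjusted p = 5.35e-10 and an adjusted p = 0.273 with an estimated correlation.

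**Figure D2:**
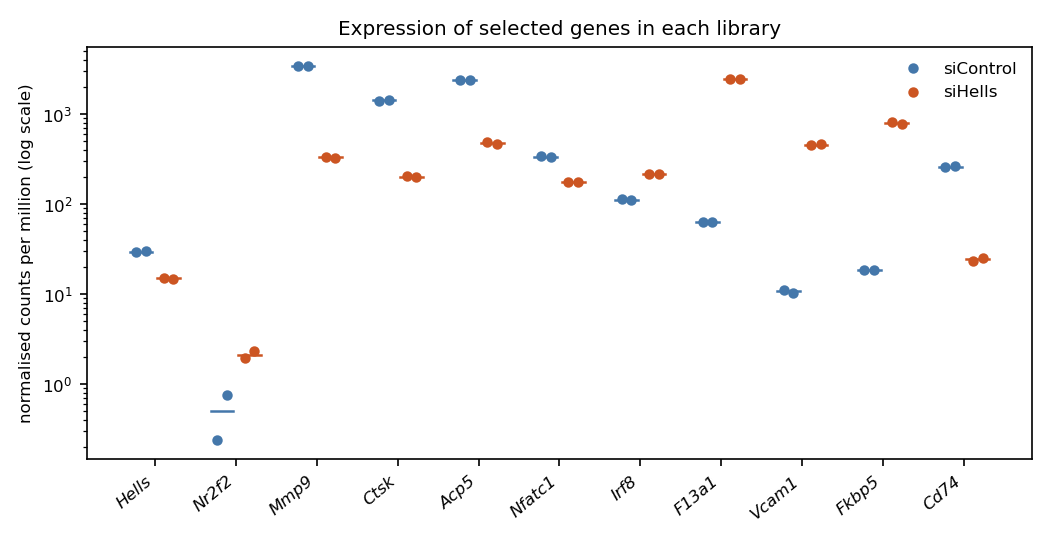
TMM-normalised CPM of 11 genes on a log axis, with a point for each library (2 per group) and a line at the group mean. Hells was lower by a log2 fold change of -0.99, Mmp9, Ctsk, Acp5, Nfatc1 and Cd74 were lower, and Nr2f2, Irf8, F13a1, Vcam1 and Fkbp5 were higher in both siHells libraries than in both siControl libraries.

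The 10 largest rises were led by Hif3a, a subunit of the hypoxia-inducible factor family, with 6 and 3 counts in siControl and 2260 and 2091 in siHells. The ratio of its summed counts was 471, with a 95% interval of 248 to 1030. Jaml, a leukocyte adhesion molecule, rose 175.9-fold to 330 ± 8.65 CPM, and Saa3, an acute-phase serum amyloid, rose 175.9-fold to 146 ± 6.19 CPM (SD, n = 2). Cd38, an enzyme that consumes NAD, rose 88.4-fold, Zbtb16, a zinc-finger transcription factor, 63.7-fold, Fkbp5, a co-chaperone of steroid receptors, 43.3-fold and Vcam1, an adhesion molecule, 42.8-fold. Ms4a8a, of the membrane-spanning 4A family, rose 48.9-fold, and Lyve1, a hyaluronan receptor found on tissue macrophages, had a ratio of summed counts of 48.8 (95% interval 26.3 to 102). Saa3 and Ms4a8a belong to families of similar genes among which reads may be split.

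The 10 largest falls included 3 genes of antigen presentation by MHC class II. H2-Eb1 fell 27.1-fold, to 1.47 ± 0.186 CPM, H2-Aa 19.5-fold, to 2.98 ± 0.245 CPM, and Ciita, the transactivator of the class II genes, 19.7-fold (SD, n = 2 each; adjusted p = 8.20e-15 for H2-Eb1). Itgax, an integrin of dendritic cells and some macrophages, fell 15.9-fold, and Siglec15, a sialic-acid receptor needed for osteoclast function, 16.0-fold. Spint2, a serine protease inhibitor, fell 16.9-fold, the protease Corin 16.6-fold and the aldo-keto reductase Akr1c18 18.3-fold. Adig, known from adipocytes, had 253 and 234 counts in siControl and 2 and 9 in siHells, and its summed counts were lower by a ratio of 45.5 (95% interval 25.2 to 91.7). Adgrf1, an adhesion receptor, was lower by a ratio of 30.8 (20.8 to 47.4). The size of these low-count falls rested partly on single libraries. The log2 fold change of Adig was -4.77 without siHells replicate 1 and -6.89 without siHells replicate 2. In the same order, that of Adgrf1 was -4.38 and -5.82, that of Corin -3.54 and -4.84, and that of Akr1c18 -4.88 and -3.73.

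Transcripts for mitochondrial respiration were lower across the nuclear and mitochondrial genomes. For complex I, all 37 nuclear genes tested fell, over all genes and when adjusted over the list alone, among them Ndufs1 (1.64-fold) and Ndufa10 (1.74-fold). The median log2 fold change of this list was -0.61, with a camera adjusted p = 4.47e-12 and an adjusted p = 0.273 with an estimated correlation. In complexes II to V, 39 of 40 nuclear genes fell (40 when adjusted over the list alone). Cycs, which encodes cytochrome c and is kept on this list, fell 2.51-fold, and the ATP synthase genes Atp5b, Atp5g3 and Atp5a1 fell 1.92-fold, 2.03-fold and 1.73-fold. Cyc1 had a log2 fold change of -1.08 with an adjusted p = 0.0719, and its counts in siHells were 5043 and 7141. The median of the list was -0.81, with a camera adjusted p = 6.63e-14 and an adjusted p = 0.315 with an estimated correlation. All 13 protein-coding genes of the mitochondrial genome fell (13 when adjusted over the list alone), from COX1 with a log2 fold change of -0.19 to ND3 with -1.48, and CYTB, ND1, COX2 and COX3 fell by 1.04, 1.26, 0.88 and 0.95. Their median was -0.88, with a camera adjusted p = 3.70e-06 and an adjusted p = 0.317 with an estimated correlation. These 13 genes held 3.27% and 3.18% of the counts in siControl and 2.02% in each siHells library.

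The tricarboxylic acid cycle and the mitochondrial ribosome moved the same way. All 23 cycle genes fell (23 when adjusted over the list alone), with Mdh2, malate dehydrogenase, 2.38-fold lower, Pdhb 2.22-fold and Sdha 1.75-fold. The median was -0.76, with a camera adjusted p = 9.54e-10 and an adjusted p = 0.273 with an estimated correlation. Of 77 mitochondrial ribosomal protein genes 72 fell and 1, Mrpl24 (log2 fold change 0.14), rose (73 and 1 when adjusted over the list alone), for a median of -0.44, a camera adjusted p = 2.16e-13 and an adjusted p = 0.273 with an estimated correlation. Mrps6 fell 4.87-fold, Mrps35 2.23-fold, Mrpl12 1.93-fold and Mrpl51 1.87-fold. Cytosolic ribosomal protein genes and genes used as references also fell, each list with a median of -0.37. Both lists were called by camera with the preset correlation (adjusted p = 6.63e-14 and 0.0194). With an estimated correlation their adjusted p was 0.412 and 0.364. The reference list itself includes Sdha.

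Regulators of mitochondrial biogenesis were mixed, with 8 of 20 genes lower and 3 higher (8 and 3 when adjusted over the list alone; camera adjusted p = 0.145). Ppargc1b, a coactivator of mitochondrial biogenesis in osteoclasts, fell 2.79-fold, its partner receptor Esrra 1.36-fold and Tfam, which packages and transcribes mitochondrial DNA, 1.18-fold (adjusted p = 0.00441). Lonp1 and Gabpa both fell 1.26-fold, and the 3 genes that rose were Nrf1 (log2 fold change 0.22), Polg (0.23) and Slc25a33 (0.51). Among genes of mitochondrial fission, fusion and mitophagy, 16 of 30 fell and 5 rose (16 and 5 when adjusted over the list alone; camera adjusted p = 0.0735, 0.0457 with gene length correction, and adjusted p = 0.317 with an estimated correlation). Phb2, Dnm1l, Immt and Sqstm1 fell by 0.82, 0.73, 0.62 and 0.54 on the log2 scale. The 5 that rose were Pink1 (0.62), Gabarapl1 (0.50), Map1lc3b (0.21), Fis1 (0.14) and Tax1bp1 (0.12). In the integrated and mitochondrial stress response, 15 of 38 genes were higher and 16 lower (15 and 17 when adjusted over the list alone; camera adjusted p = 0.865, fry adjusted p = 0.00316). Ddit4, an inhibitor of mTORC1 signalling, rose 37.7-fold and Vldlr 3.18-fold, while the mitochondrial chaperones Hspd1 and Hspa9 fell 1.79-fold and 1.57-fold. Ddit4 is also among the glucocorticoid targets described below.

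Glycolysis genes fell more often than they rose, 15 against 4 of 20 (15 and 4 when adjusted over the list alone), with a median log2 fold change of -0.33, a camera adjusted p = 0.0140 and an adjusted p = 0.317 with an estimated correlation. Reference genes and cytosolic ribosomal protein genes fell beside them, each list with a median of -0.37. Camera called both with the preset correlation (adjusted p = 0.0194 and 6.63e-14). With an estimated correlation their adjusted p was 0.364 and 0.412. The reference list includes metabolic genes such as Gapdh and Sdha, so it is not an independent baseline. Aldoc fell 8.91-fold, Ldha 1.56-fold and Eno1 1.53-fold. The 4 that rose were Pfkfb3 (5.41-fold), which makes the activator of phosphofructokinase, Hk2 (log2 fold change 0.74), Pfkl (0.55) and Slc2a1 (0.19). Of 28 antioxidant genes 12 rose and 10 fell (12 and 10 when adjusted over the list alone; camera adjusted p = 0.744). Hmox1 and Cat rose 1.60-fold and 1.65-fold, and Sod1 and Txn1 fell 1.96-fold and 1.76-fold.

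Proliferation genes fell, beside cytosolic ribosomal protein genes and reference genes, each with a median of -0.37. The ribosomal and reference lists had a camera adjusted p = 6.63e-14 and 0.0194, against 0.412 and 0.364 with an estimated correlation. In mitosis, 65 of 69 genes fell and 1, Pttg1 (log2 fold change 0.43), rose (65 and 1 when adjusted over the list alone). Espl1, the separase, fell 2.49-fold, Bub1b 1.77-fold, Top2a 1.73-fold and Mki67 1.43-fold. The median was -0.64, with a camera adjusted p = 4.11e-14 and an adjusted p = 0.273 with an estimated correlation. In DNA replication, 45 of 56 genes fell and 2, Rfc1 (0.19) and Pold3 (0.29), rose (47 and 2 when adjusted over the list alone). Chaf1b fell 2.09-fold, Uhrf1 1.69-fold, Mcm5 1.61-fold and Rrm1 1.46-fold. That list had a median of -0.46, a camera adjusted p = 1.86e-09 and an adjusted p = 0.285 with an estimated correlation. Among p53 target and DNA damage genes, 23 of 36 rose and 8 fell (24 and 8 when adjusted over the list alone), with a median of 0.32, a camera adjusted p = 0.0101 and an adjusted p = 0.317 with an estimated correlation. The members with the smallest p were Dusp1 (7.06-fold), a phosphatase of MAP kinases that other stimuli also induce, Btg2 (2.33-fold), Sesn2 (2.13-fold) and Zmat3 (1.77-fold), and the cell-cycle inhibitor Cdkn1a rose 1.49-fold. Apoptosis regulators went both ways, with 11 of 28 higher and 11 lower (11 and 12 when adjusted over the list alone; camera adjusted p = 0.971), for a median of 0.05 and a mean of -0.06. Bcl2l1, which opposes apoptosis, rose 1.91-fold, and Bcl2l11 and Pmaip1, which promote it, fell 1.64-fold and 1.96-fold.

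Interferon-stimulated genes rose as a list, 46 of 61 higher and 6 lower (47 and 6 when adjusted over the list alone), with a median log2 fold change of 0.49, a camera adjusted p = 7.13e-09 and an adjusted p = 0.273 with an estimated correlation. Ly6a rose 7.84-fold, Ifi204 3.29-fold, Ifi209 3.07-fold and Ly6e 2.63-fold, and Ifi204 and Ifi209 are neighbours in a family of similar genes among which reads may be split. Cxcl10 fell 4.45-fold, Isg15 fell by 0.20 on the log2 scale, and Ifit1 had a log2 fold change of -0.02 (adjusted p = 0.805). Inflammatory NF-kB targets went both ways, with 18 of 35 lower and 10 higher (19 and 10 when adjusted over the list alone; camera adjusted p = 0.473). Traf1 fell 3.83-fold, Il1rn, the interleukin-1 receptor antagonist, 2.91-fold and the chemokine Ccl9 1.87-fold. The list had a median of -0.17 and a mean of 0.05, which Saa3 raised.

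Chromatin, germline and imprinting lists were not called by camera and were called by fry (adjusted p = 0.0294, 0.0311 and 0.0355). Of 38 genes for DNA methylation and heterochromatin 14 rose and 17 fell (14 and 17 when adjusted over the list alone; camera adjusted p = 0.865), for a median of 0.01 and a mean of -0.11. Dnmt3a, a de novo DNA methyltransferase, fell 2.37-fold, Uhrf1, which recruits the maintenance methyltransferase, 1.69-fold, and the dioxygenase Tet3 rose 1.39-fold. Germline genes that DNA methylation keeps silent could be tested for 15 of 57 listed members. A gene with 0 reads in even 1 library is absent from the table and was not analysed here. Whether some listed symbols were missing for their naming instead was not checked. Of these 6 fell and 1 rose (6 and 1 when adjusted over the list alone; camera adjusted p = 0.236). The gene that rose was Dpep3, with 24 and 15 counts in siControl and 95 and 85 in siHells, while Tdrkh fell by 0.59 on the log2 scale and Xlr4a fell 1.86-fold. Xlr4b fell by 0.46 on the log2 scale and did not pass without siHells replicate 1 (-0.34, adjusted p = 0.0602). Xlr4a and Xlr4b are close copies whose reads may be shared. Among 29 imprinted genes 10 rose and 6 fell (10 and 6 when adjusted over the list alone; camera adjusted p = 0.283). Dcn, also on the list of osteoblast, stromal and endothelial markers, rose 4.93-fold, Grb10 1.95-fold and Peg13 1.80-fold, and Igf2r fell 1.41-fold. Nuclear receptor genes were split, with 8 of 25 higher, Nr2f2 included, and 9 lower (8 and 10 when adjusted over the list alone; camera adjusted p = 0.904). Rara rose 2.24-fold, Rxra had a log2 fold change of 1.07 and Nr1d2 fell 1.81-fold.

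In the lysosome and proton pump list 23 of 45 genes fell and 18 rose (23 and 18 when adjusted over the list alone; camera adjusted p = 0.532). Proton pump subunits Atp6v1d and Atp6v1b2 fell 2.69-fold and 2.39-fold, while the lysosomal genes Psap and Ctsb rose 1.81-fold and 1.72-fold. Iron-handling genes fell in 11 of 18 cases and rose in 5 (11 and 5 when adjusted over the list alone; camera adjusted p = 0.273). Tfrc, the transferrin receptor, fell 2.79-fold and Ncoa4, the receptor for ferritin turnover, 2.13-fold. The 5 that rose were Fbxl5 (3.59-fold), Slc11a1 (1.93-fold), Hmox1 (1.60-fold), Slc40a1 (log2 fold change 0.52) and Slc25a37 (0.44). Among cholesterol genes 9 of 24 were lower and 5 higher (9 and 5 when adjusted over the list alone; camera adjusted p = 0.512, fry adjusted p = 0.0170). Nsdhl, an enzyme of cholesterol synthesis, fell 1.36-fold. The 5 that rose were Mvk (1.32-fold), Sqle (0.35 on the log2 scale), Pmvk (0.27), Tm7sf2 (0.50) and Stard4 (0.20).

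Markers of other marrow cells moved in several directions beside these groups. Osteoblast, stromal and endothelial markers were higher for 12 of 26 genes and lower for 4 (12 and 4 when adjusted over the list alone; median 0.34, camera adjusted p = 0.0541). Col1a1, Col1a2 and Acta2 rose to 617 ± 5.98, 706 ± 5.37 and 345 ± 11.4 CPM. The largest rise of this list was that of Dcn, 4.93-fold, which is also on the imprinted list. The 4 that fell were Spp1 (2.56-fold), which osteoclasts also express, Runx2 (log2 fold change -0.42), Col3a1 (-0.40) and Vwf (-1.11). The list passed with library totals as the scaling (adjusted p = 0.0285) and without siHells replicate 2 (adjusted p = 0.0467), and had an adjusted p = 0.420 with an estimated correlation. Dendritic cell markers were lower for 6 of 13 genes and higher for 3 (7 and 3 when adjusted over the list alone; camera adjusted p = 0.0575). The 3 that rose were Flt3 (log2 fold change 2.50), Zbtb46 (0.50) and Bst2 (0.27), and those that fell were 5 class II genes, Cd74 among them (10.8-fold), and Itgax. That list passed without siControl replicate 1, siHells replicate 1 or siHells replicate 2 (adjusted p = 0.0488, 0.0169 and 0.0167), and had an adjusted p = 0.317 with an estimated correlation. Lymphocyte and NK cell markers were lower for 5 of 9 genes and higher for 1, Ebf1 (5 and 1 when adjusted over the list alone), with a median of -0.98, a camera adjusted p = 0.0443 and an adjusted p = 0.317 with an estimated correlation. The 5 were Cd4 (2.62-fold), Ighm (4.11-fold), Trac (4.11-fold), Lck (19 and 16 counts in siControl, 3 and 3 in siHells) and Il7r (log2 fold change -0.32). This call was lost without siControl replicate 2 (adjusted p = 0.0673) and without siHells replicate 1 (adjusted p = 0.0773). It was also lost with library totals (adjusted p = 0.0603), a stricter filter (adjusted p = 0.153) and gene length correction (adjusted p = 0.0676).

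Neutrophil markers rose for 4 of 15 genes and fell for 5 (4 and 5 when adjusted over the list alone; camera adjusted p = 0.971). Mmp8 rose 4.25-fold and Lcn2 1.80-fold, as did Csf3r (log2 fold change 0.14) and Retnlg (0.93), while Camp fell 2.82-fold and Ltf 2.22-fold, as did Mpo (-0.19), Ngp (-0.38) and S100a9 (-0.12). Erythroid, megakaryocyte and mast cell markers rose for 5 of 10 genes and fell for 1, Kit (5 and 1 when adjusted over the list alone; camera adjusted p = 0.173). Those that rose were Pf4 (3.24-fold), which macrophages can also express, Itga2b (3.73-fold), Gata2 (2.81-fold), Cpa3 (3 and 7 counts in siControl, 18 and 13 in siHells) and Ppbp (log2 fold change 1.02).

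Cytosolic ribosomal protein genes fell for 73 of 75 members (73 when adjusted over the list alone), by a median of -0.37 on the log2 scale, with a camera adjusted p = 6.63e-14 and an adjusted p = 0.412 with an estimated correlation. Rpl12 fell 1.58-fold, Rpl23a 1.57-fold, Rpl13a 1.44-fold and Rpl4 1.42-fold, and pseudogenes of these genes may take part of their reads. The list held 4.51% and 4.56% of the counts in siControl and 3.36% and 3.29% in siHells. Among 18 genes used as references 13 fell and 4 rose (13 and 4 when adjusted over the list alone; median -0.37, camera adjusted p = 0.0194, adjusted p = 0.364 with an estimated correlation). Tfrc fell most, 2.79-fold, Sdha fell 1.75-fold, and Gapdh and Ppia fell 1.54-fold and 1.59-fold. Tfrc is also on the iron list and Sdha on the tricarboxylic acid cycle list, so the reference genes are not independent of those lists. Those that rose included B2m (log2 fold change 0.51), Gusb (0.42) and Hprt (0.12). Immediate-early and heat shock genes, which respond to handling, rose for 11 of 22 members and fell for 6 (11 and 6 when adjusted over the list alone; camera adjusted p = 0.239), with Dusp1 and Btg2 higher and Fos and Hsp90aa1 lower by 1.83-fold and 1.61-fold.

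**Figure D3:**
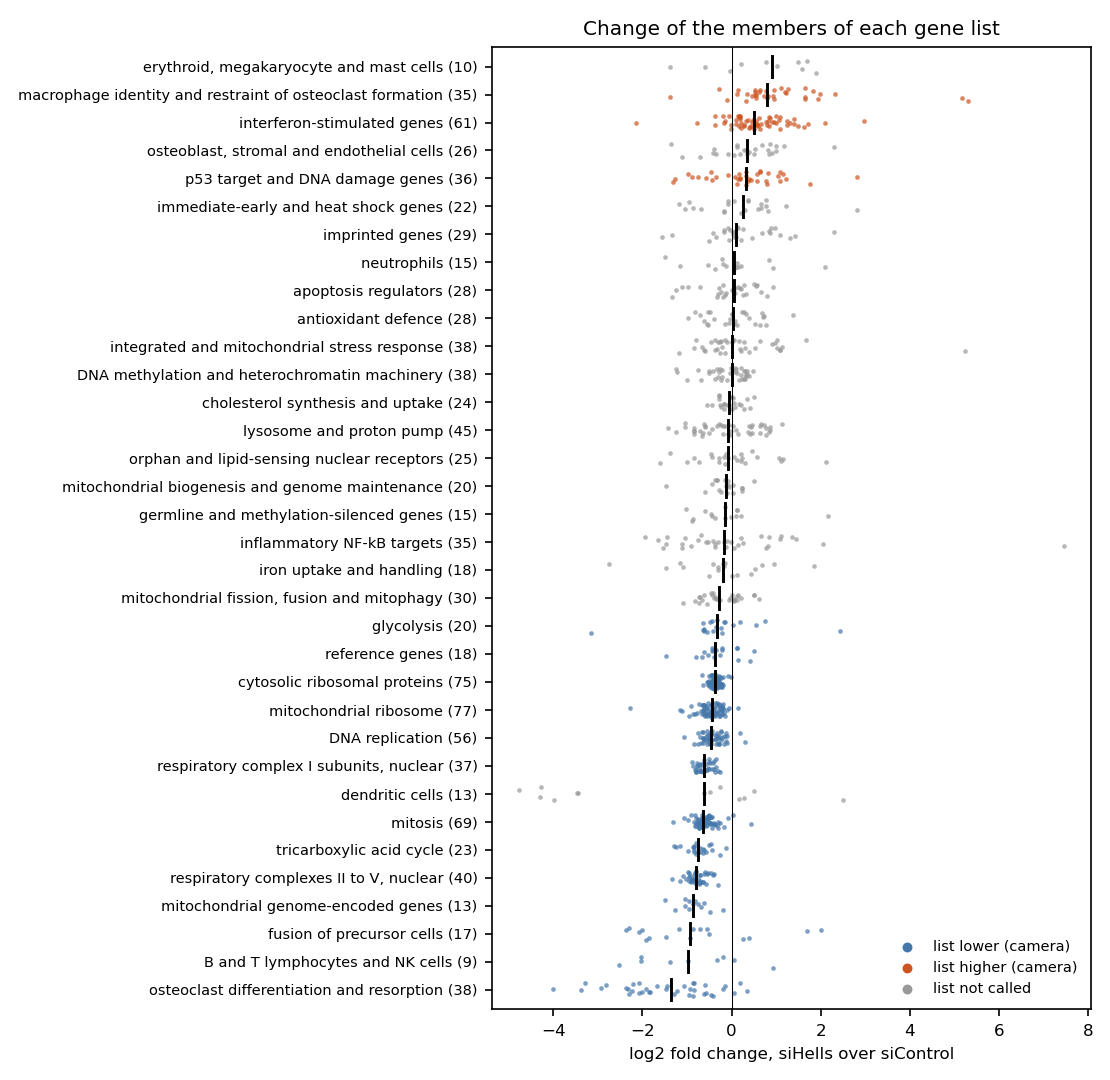
Log2 fold change of siHells over siControl for each tested member (points) of the 34 gene lists, with the median as a black bar, the number of members in brackets and colour for lists past an adjusted p of 0.05 by camera. Osteoclast genes have the lowest median at -1.36 and the macrophage list stands at 0.80.

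Of the 34 lists, 13 were lower and 3 higher with the preset correlation of 0.01. With a correlation estimated for each list camera called 0 of them, while 4 had an unadjusted p below 0.05, the smallest being 0.0127. With 2 residual degrees of freedom that form could hardly pass after adjustment over 34 lists, so it decides little either way. The test fry called 32, and it asks whether a list's genes move 1 way on balance without comparing them with other genes.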

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

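Corrections for gene length and GC content were chosen after the data had been seen. Hells and Nr2f2 kept their direction and call under all 16 alternatives each. The number of genes called was 9153. At the same threshold it ranged from 7809, without siControl replicate 1, to 9281, with library totals, and the DESeq2 Wald test called 7931. With a library left out, the lone sample is assumed to vary like the other group. Of 4541 genes higher and 4612 genes lower, a test against a 1.5-fold change kept 1261 genes higher and 1096 genes lower, and an adjusted p below 0.01 kept 3704 genes higher and 3793 genes lower. Of the calls, 49.6% were higher, and 40.7% were with library totals. Among genes called, 0 changed sign under any alternative except gene length correction, which turned 62. Across named genes and alternatives, 2391 results were the same and 1 was weaker, that of Xlr4b. Across lists, 363 were the same, 21 weaker, 20 stronger and 2 reversed. With an estimated correlation, a form of little power at 2 residual degrees of freedom, camera called 0 lists lower and 0 higher. With the preset correlation 13 and 3 had been called, and fry called 23 lower and 9 higher, by a different null hypothesis. Apoptosis regulators and neutrophils had the other direction with fry (adjusted p = 0.0396 and 0.0373), where camera had called neither, and the cause was not tested.

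The labels give the groups the same replicate numbers, and same-numbered libraries deviated together with a correlation of 0.0499, so the numbers were not taken as pairs. With a replicate block, 4502 genes higher and 4586 genes lower were called, 9088 in all, of which 8959 were also called without it.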

Other observations

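The lists of known glucocorticoid receptor targets and the tests of Nr3c1, Fkbp5 and dendritic cell markers were chosen only after the result was seen, and the gene length and GC corrections were added after the data had been seen.

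Genes that glucocorticoids induce rose strongly in siHells. Tsc22d3, an anti-inflammatory leucine zipper protein, rose 12.8-fold, from 63.1 ± 1.06 to 809 ± 4.56 CPM (SD, n = 2 each). The circadian regulator Per1 rose 8.28-fold, the scavenger receptor Cd163 had a log2 fold change of 5.18, the sulfotransferase Sult1a1 3.94 and the transcription factor Klf9 3.40. Of 26 such genes listed with their values in view, 24 rose and 2, Anxa1 (-0.88) and Nfkbia (-0.29), fell. Of the 26, 6 also stand in a list fixed beforehand. They include Mertk, Ddit4 and Dusp1, whose rises are therefore not independent of those lists.

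These targets include Fkbp5, Hif3a and Zbtb16, 3 of the largest rises. A further 15 known targets, listed without their values in view, 1 of which also stands in a list fixed beforehand, had a median log2 fold change of 0.81, with 11 higher and 1, Cdkn1c, lower, against at most 0.73 in 10000 random lists matched for expression. Higher glucocorticoid receptor activity in the siHells libraries is a candidate explanation. The receptor transcript Nr3c1 was not higher on day 2, at a log2 fold change of -0.28, and earlier times were not measured. With Fkbp5 at a log2 fold change of 5.44, an effect of the siRNA cannot be told apart from a steroid exposure that differed between the cultures, because any such exposure coincides with the groups.

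Genes of the nuclear respiratory complexes and of the mitochondrial and cytosolic ribosomes fell together, with a median log2 fold change of -0.45 over 229 genes. A length or GC bias between the libraries could give such a pattern. After removal of the length trend the median was -0.39 in the 228 genes with a length, 205 were still lower and called, and the largest adjusted p of the lists was 8.24e-10. Before any correction, the adjusted p of these lists was 0.273 to 0.412 with an estimated correlation. After removal of the GC trend the median was -0.447, with 220 lower and called, so neither trend is the whole cause, and a real change in these transcripts remains a hypothesis.

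The 5 genes of the MHC class II pathway fell, with a median log2 fold change of -4.28. Fewer dendritic cells in the siHells cultures could give this. The 8 other dendritic cell markers had a median of -0.039. Their median absolute deviation, scaled to estimate an SD, was 0.73. Flt3 and Zbtb46 were higher, at 2.50 and 0.50, and Itgax was lower, at -3.99. These values show only that the markers outside the class II pathway did not all fall. Of the 13 dendritic cell markers tested, 4 did not pass the threshold. The markers were few and the rule was set after their values were seen, so they cannot decide whether dendritic cells were lost. A loss of cells rich in both Itgax and class II transcripts, or a fall within macrophages, stays open and was not tested.

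Of the 56 DNA replication genes, with a median log2 fold change of -0.46 and an SD of 0.24, only Chaf1b fell as much as Hells, at -0.99, did.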
